A study of Mus musculus with 9 samples.

How the data were processed

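Polyadenylated or total RNA selection is not given in the sources used here; libraries were made with the VAHTS Universal V6 kit, per the labels' protocols, and whether counting used strand is not stated. The study holds 9 libraries of mouse bone-marrow-derived macrophages in 3 groups of 3, control, IL-4, and IL-4 followed by TMV-OEG8-Man, and each library was placed in its group by its label. A count table of the whole series and a table of FPKM per library were used. The count values are the authors' whole-number read counts per gene, deposited without normalization. The submitters' processing notes name fastp 0.20.1, HISAT2, HTSeq 0.11.2, DESeq2 1.22.2 and the mouse build GRCm39, without a role or an order for any of them. The FPKM values are those the authors deposited, and over 11627 genes with at least 10 counts they equalled the deposited counts divided by a fixed length per gene and by the library's total, with a largest relative deviation of 4.42e-08. They were used only in alternatives. All 9 columns of the count table matched a sample, and 0 were left unmatched.

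The reference held here was built on another mouse assembly than the one the notes name, so no coordinates are given and it served for names only, where 20499 of 21487 symbols matched. Counts of genes that share sequence with close relatives (such as Chil3 and Chil4, the Retnla family, Rnase2a, the Ifit family, and H2-Q6, H2-Q7 and H2-D1) are uncertain, since the counting could split or leave out their reads. The same holds for overlapping genes and antisense partners.

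Library totals ran from 35661297 to 37854967 counts, and the genes with at least 1 count from 17667 to 17815 in control, 16754 to 17096 with IL-4 and 16410 to 16565 with TMV-OEG8-Man. TMM factors were 1.14 to 1.15, 0.96 to 0.99 and 0.87 to 0.91. The gene with most counts was Apoe or Lyz2 in control (2.389% to 2.467% of a library), Ctsb with IL-4 (2.264% to 2.35%) and Fth1 with TMV-OEG8-Man (4.399% to 4.58%). Spearman correlations between replicates were 0.99496 to 0.99686, and no pair of replicates was the same within sampling noise.

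Genes were tested in R 4.3.3 with edgeR 4.0.16. Genes were filtered by filterByExpr, which left 14114, scaled by TMM, and fitted by a robust quasi-likelihood model with 1 mean per group over all 9 libraries, leaving 6 residual degrees of freedom. The biological coefficient of variation was 6.17%. Each comparison was a contrast of 2 groups, two-sided, with Benjamini-Hochberg adjustment over the genes tested, and a call is an adjusted p under 0.05. A fold is the ratio of the 2 groups' counts, each summed over its 3 libraries and divided by the sum of their TMM-scaled library sizes. Against 0 counts it is a lower bound, taking 3 counts over the 3 libraries of the group, and against 1 to 3 counts it is a ratio with a 95% counting interval. Log2 fold changes are those of the edgeR fit, so they can differ somewhat from the log2 of a fold. CPM values are TMM-scaled.

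Gene lists were tested by camera in limma 3.58.1 on log2 CPM with a prior count of 2 and a preset correlation of 0.01, adjusted over the 33 lists with at least 5 measured members. The 35 lists cover alternative activation, classical activation, NF-kB targets and inflammatory cytokines, the type I interferon response, profibrotic macrophage products, matrix-degrading enzymes, mannose-binding and C-type lectin receptors, Toll-like receptors and nucleic acid sensing, MHC class II and class I presentation, S phase, mitosis, glycolysis, hypoxia, nuclear-encoded and mitochondrially encoded respiratory chain transcripts, fatty acid oxidation, cholesterol synthesis, cholesterol efflux and LXR targets, lysosome, NRF2 targets, unfolded protein and amino acid response, heat shock and core macrophage genes. Further lists hold markers of neutrophils, B cells, T and NK cells, dendritic cells, mast cells with basophils and eosinophils, fibroblasts with stromal and endothelial cells, the erythroid and megakaryocyte lines and osteoclasts, and ribosomal protein, histone and immediate early genes. They name 994 genes, of which 919 matched by the same symbol, 13 by a mitochondrial symbol and 13 by an older or newer symbol, while 2 were a second name of a member and 47 were not matched.

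The design, lists, alternatives and rule for named genes were fixed before the data were examined. The rule takes, per comparison, the 8 highest and 8 lowest log2 fold changes among called genes with a mean of at least 5 CPM over both groups, non-overlapping CPM and a symbol that is not a predicted, clone, pseudogene or locus name. It adds, per list described, up to 3 called members with the largest absolute log2 fold change and a mean of at least 1 CPM, or where none is called up to 2 with the highest CPM. It also adds Arg1, Chil3, Retnla, Mrc1, Nos2, Il1b, Tnf, Il6, Cd86, Tgfb1, Il10 and Il4ra in every comparison. A gene named in one comparison may have its value given in the others. For 2 genes that the rule takes, the values are not reported here.

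The alternatives were RLE and upper-quartile factors, no low-count filter, at least 1 CPM in at least 3 libraries, DESeq2 1.42.0, limma-voom, only the 2 groups compared, a replicate block, limma-trend on log2(FPKM + 1) and log2(FPKM + 0.1), a further condition of at least 2-fold, and leaving out each library in turn. For lists they were an estimated correlation, fry, the block, no filter and leaving out each library. Scaling by total count was added later. The moved-back genes were set against 20 simulations without effects and against independent lists.

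The tests were tried on simulated data drawn from the real means of the group compared against and the real library sizes, with 50 genes changed at each of 1.5, 2, 4 and 8-fold. As many were raised as lowered and all other genes were unchanged. These trials thus do not cover errors of scaling where most genes change, as in the data. A changed gene that the low-count filter removed in a trial was scored as not recovered. The shares recovered thus mix loss by the filter with misses of the test. For IL-4 versus control, over 13607 genes, 68%, 72%, 96% and 86% were recovered and 11 of 13418 unchanged genes were called. For TMV-OEG8-Man versus IL-4, over 13290 genes, 70%, 80%, 88% and 96% were recovered, with 6 of 13095 unchanged genes called. For TMV-OEG8-Man versus control, over 13592 genes, 68%, 76%, 90% and 98% were recovered, with 13 of 13395 called.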

Results

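RNA sequencing was done on 9 libraries of macrophages grown from the bone marrow of female Balb/c mice with 25 ng/mL M-CSF, the growth factor that turns marrow progenitors into macrophages, and taken as mature on day 6. Of these, 3 came from resting cells, the control group, which were left untreated and given fresh medium when the other cells were stimulated. A further 3 came from cells given 25 ng/mL IL-4 for 48 h, a cytokine that drives the alternative, or M2, form of macrophage activation. The last 3 came from cells given the same IL-4 and then, in replaced medium, 50 µg/mL TMV-OEG8-Man for 24 h. By the title of the series this is a mannose-modified tobacco mosaic virus, a rod-shaped plant virus, which the study examined as a regulator of macrophages in pulmonary fibrosis. Each library held between 35661297 and 37854967 counts over 21487 genes, and 14114 genes passed the filter on low counts. Levels are given as mean CPM, counts scaled to library size, ± SD over the n = 3 libraries of a group. The groups lay apart on the first 2 principal components, which held 69.01% and 21.69% of the variance. Replicates of a group differed by more than sampling noise, with a chi-square per gene between 4.156 and 8.388. The labels do not say that the 3 libraries of a group came from separate cultures or animals, so p-values measure only the spread between these samples, which may be technical.

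The first comparison asked what 48 h of IL-4 changed in resting macrophages. Genes of alternative activation that were nearly silent in control cells became some of the most abundant transcripts. Arg1, the arginase that turns arginine into ornithine and urea, rose 3308-fold, from 0.425 ± 0.229 to 1411 ± 45.3 CPM (SD, n = 3). Retnla, a secreted resistin-like protein, rose from 1.75 ± 0.932 to 12030 ± 512 CPM, and Chil3, a chitinase-like lectin, from 0.449 ± 0.0642 to 3032 ± 59.5 CPM. The mannose receptor gene Mrc1 rose 8.22-fold, from 149.0 ± 6.09 to 1223 ± 57.5 CPM. In the other direction the inflammatory cytokine genes Il1b and Tnf fell 10.1-fold and 9.00-fold, to 1.86 ± 0.220 and 1.33 ± 0.221 CPM.

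**Figure D1:**
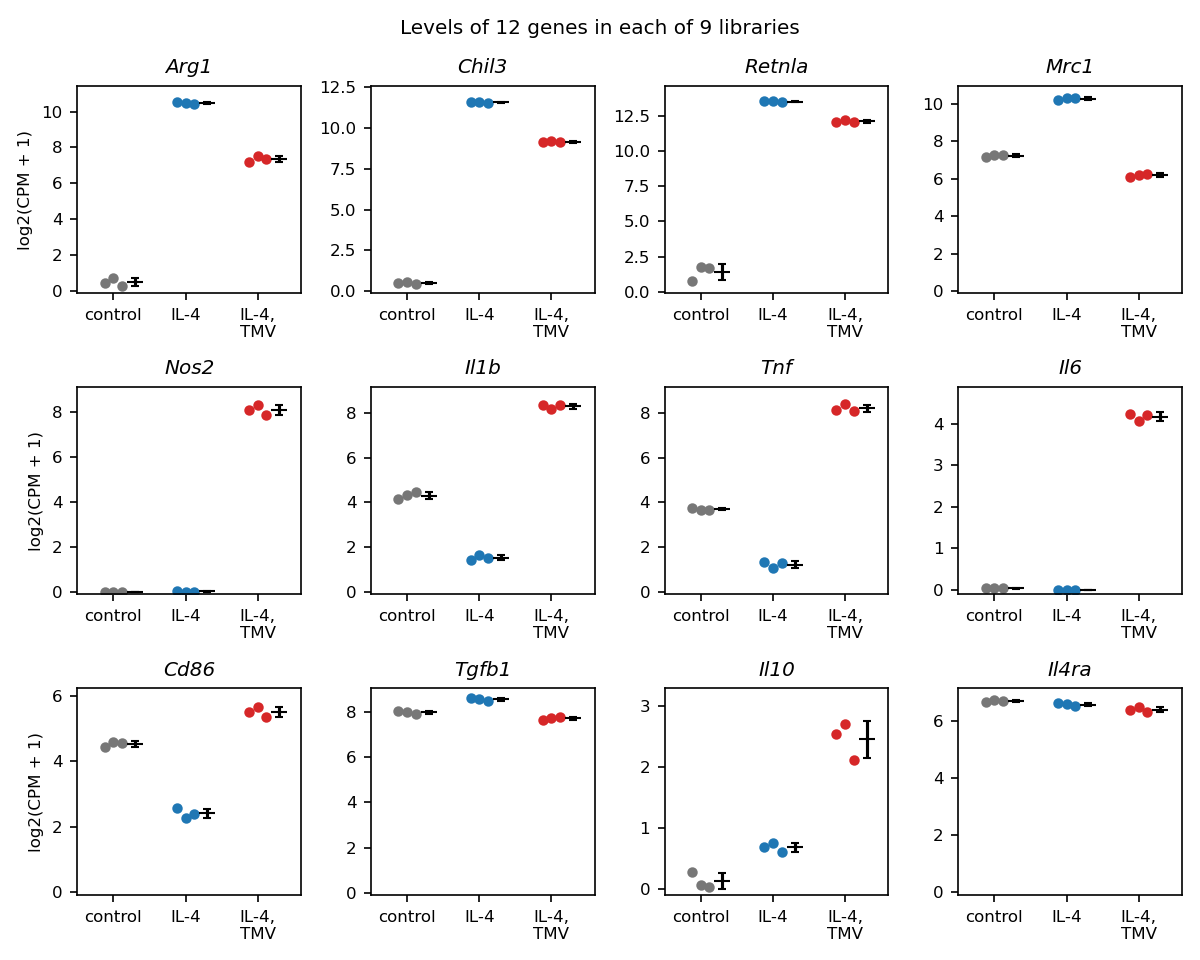
Levels of 12 genes, as log2(CPM + 1), in control, IL-4 and IL-4 then TMV-OEG8-Man (TMV) libraries; points are the 3 libraries of each group, and the bar beside them is their mean and SD on this scale. Arg1 stood at 0.425, 1411 and 162.7 CPM in the 3 groups, and Tnf at 11.98, 1.33 and 294.4 CPM.

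Among the largest rises were also Rnase2a, an eosinophil-associated ribonuclease, at 1251 ± 26.7 CPM after 0.0967 ± 0.112 in control, Mgl2, a galactose-type lectin, at 64.5 ± 7.33 CPM, and Pdcd1lg2, the PD-L2 ligand of the T cell receptor PD-1, which rose 662.0-fold. Scn3a, a sodium channel subunit, and Cldn11, a tight junction claudin, had 1 count in the control libraries together, and the ratios were 3737 (95% counting interval 670.1 to 147600) and 1752 (314.1 to 69270). Scn3a had 0 control counts without control replicate 2 and Cldn11 without control replicate 3, which left only lower bounds of 827.5-fold and 395.0-fold, and without control replicate 1 the ratios were 2464 (441.9 to 97360) and 1156 (207.1 to 45680), with 1164 (208.7 to 46020) for Cldn11 without control replicate 2. Intervals and floors on such ratios cover counting error only. Cx3cr1, the fractalkine receptor, fell 50.6-fold to 2.88 ± 1.03 CPM, and Clec4e, the Mincle receptor for microbial glycolipids, fell 33.8-fold to 0.935 ± 0.398 CPM. Falls of between 21.4-fold and 48.8-fold were also seen in Gpr162, an orphan receptor, Tspan7, a tetraspanin, Cd24a, a surface glycoprotein, Gpr84, a receptor for medium-chain fatty acids, Icosl, a ligand of a T cell costimulator, and Dio2, a deiodinase that activates thyroid hormone. The costimulator gene Cd86 fell 5.15-fold to 4.33 ± 0.536 CPM. The cytokine gene Tgfb1 rose 1.48-fold to 375.5 ± 14.9 CPM, and Il10, a cytokine that restrains inflammation, rose 6.43-fold but only to 0.609 ± 0.0827 CPM. Control replicate 1 held 9 of the 12 Il10 counts in control, and without it the ratio was 17.0 (5.55 to 84.4). Nos2, the inducible nitric oxide synthase, and Il6, an inflammatory cytokine, had at most 3 counts in either group, so no fold is given. Il4ra, a subunit of the IL-4 receptor, stood at 93.7 ± 3.59 against 101.5 ± 2.87 CPM (adjusted p = 0.0411). That call ended without control replicate 2 (adjusted p = 0.169) or 3 (0.077), without IL-4 replicate 2 (0.0694) or 3 (0.197), without TMV-OEG8-Man replicate 1 (0.0525), with RLE size factors (0.052) and with DESeq2 (0.0905).

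Of the 38 measured members of the alternative activation list, 31 rose, 4 fell and 3 were not called, with a median log2 fold change of 2.85 (adjusted p = 9.81e-18 by camera, and 0.00144 with an estimated correlation). All 3 examples with the largest change, Rnase2a, Retnla and Chil3, are named above. The classical activation list of 33 genes, those known to respond to lipopolysaccharide and interferon gamma, had 17 members lower, 3 higher and 13 not called, and its median member fell by 1.62 on the log2 scale, or by 1.74 with genes of at most 3 counts at their bound (adjusted p = 0.000465, and adjusted p = 0.086 with an estimated correlation). In it Acod1, the enzyme that makes itaconate, fell 38.4-fold to 0.206 ± 0.0550 CPM, and Ptgs2, the inducible cyclooxygenase, 15.6-fold to 1.79 ± 0.414 CPM. Among 37 type I interferon response genes 24 fell, 5 rose and 8 were not called (adjusted p = 1.46e-06, and adjusted p = 0.43 with an estimated correlation). Examples are the antiviral genes Ifit2, down 5.88-fold to 1.219 ± 0.0435 CPM, and Rtp4, down 3.73-fold to 10.99 ± 0.800 CPM. The 31 NF-kB targets and inflammatory cytokines had 9 higher and 15 lower, with a median of -0.41, a mean of 0.0502 and no call as a list (adjusted p = 0.141). There the chemokine gene Ccl8 rose to 13.05 ± 1.142 CPM while the adhesion gene Icam1 fell 5.05-fold. The counts in these 4 lists were the same adjusted over the list alone as over all genes tested, except 5 higher in the classical activation list and 25 lower in the interferon list.

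Of 11 measured MHC class II genes 10 rose and 1 was not called, with a median of 3.32 (adjusted p = 6.31e-13, and adjusted p = 0.086 with an estimated correlation). Cd74, the invariant chain that escorts class II molecules, rose 12.04-fold to 7114 ± 356 CPM, and H2-Eb1, a class II beta chain, 11.4-fold to 589.2 ± 29.8 CPM. Of 19 MHC class I genes 11 rose, 1 fell and 7 were not called, with a median of 0.25, which fell to 0.014 with total counts (adjusted p = 0.00112, and adjusted p = 0.194 with an estimated correlation). Psmb10, a subunit of the immunoproteasome, rose 1.91-fold. The counts adjusted over the list alone were 10 higher and 0 lower for class II, and 11 and 2 for class I.

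The profibrotic list, 36 products of macrophages linked to scarring, was divided, with 15 members higher, 15 lower and 6 not called, both over all genes and adjusted over the list alone, and a median of 0.056, which turned to -0.18 with total counts and to -0.0021 with upper-quartile scaling (adjusted p = 0.615). Of its 36 genes 16 are also in other lists, among them Arg1 and Ccl24. Fn1, the matrix protein fibronectin, rose 5.35-fold to 4500 ± 91.6 CPM, Igf1, a growth factor, 4.80-fold to 1844 ± 84.8 CPM, and Ccl24, a chemokine for eosinophils, 514.1-fold to 56.9 ± 4.30 CPM. Ccn2, a matricellular growth factor, fell 6.59-fold to 40.1 ± 8.20 CPM. Fn1 and Igf1 were named here after their values were seen. Markers of fibroblasts, stromal and endothelial cells were lower in the same libraries. Of 19 such genes 15 fell, 2 rose and 2 were not called, with 16 lower adjusted over the list alone, and the median member fell by 1.58 on the log2 scale (adjusted p = 1.63e-05, and adjusted p = 0.43 with an estimated correlation). Pdgfrb, a growth factor receptor of mural cells, fell 6.44-fold to 4.10 ± 1.30 CPM, and the smooth muscle gene Tagln 5.08-fold to 24.0 ± 8.50 CPM. Sparc is in both lists. The list of matrix metalloproteinases and matrix-degrading enzymes had 13 of 23 members higher and 4 lower, with the same counts adjusted over the list alone (adjusted p = 0.00141, and adjusted p = 0.086 with an estimated correlation). Mmp12, the macrophage elastase, rose 5.49-fold to 969.0 ± 4.10 CPM, while Plau, urokinase, fell 3.81-fold.

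Among the 24 mannose-binding and C-type lectin receptors 14 rose and 9 fell, also adjusted over the list alone, with a median of 0.98, or 1.39 with genes of at most 3 counts at their bound (adjusted p = 0.109, and 0.0165 with no low-count filter). The 35 Toll-like receptor and nucleic acid sensing genes had 16 higher and 14 lower, with a median of 0.10, which turned to -0.14 with total counts, and a mean of -0.091 (adjusted p = 0.679), or 17 and 14 adjusted over the list alone. Tlr2, a receptor for bacterial lipoproteins, fell 5.59-fold to 31.1 ± 2.31 CPM, and Cd14, a co-receptor for lipopolysaccharide, 2.95-fold to 107.9 ± 4.09 CPM.

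The lysosome list had 37 of 52 members higher and 9 lower, with a median of 0.26 (adjusted p = 5.38e-08, and adjusted p = 0.43 with an estimated correlation). Its largest rises were in Acp5, the tartrate-resistant phosphatase, 10.7-fold to 154.4 ± 8.52 CPM, and Atp6v0d2, a proton pump subunit, 6.34-fold to 1273 ± 71.8 CPM. Fatty acid oxidation had 22 of 30 higher and 2 lower (median 0.27, adjusted p = 6.88e-05, and adjusted p = 0.086 with an estimated correlation), with Hadhb, a subunit of the mitochondrial trifunctional protein, up 1.80-fold to 78.2 ± 7.07 CPM and Pdk4, a kinase that restrains pyruvate oxidation, down 4.67-fold. Cholesterol efflux and LXR target genes had 11 of 17 higher and 3 lower (median 0.31, adjusted p = 0.00492, and adjusted p = 0.086 with an estimated correlation), among them Pltp, a phospholipid transfer protein, up 3.46-fold to 1943 ± 56.9 CPM. Nuclear-encoded oxidative phosphorylation had 38 of 53 higher and 1 lower with a median of 0.22, which turned to -0.025 when libraries were scaled by total count (adjusted p = 7.36e-07, and adjusted p = 0.43 with an estimated correlation). NRF2 targets had 15 of 26 higher and 5 lower with a median of 0.22, which turned to -0.017 with total counts (adjusted p = 0.00127, and adjusted p = 0.43 with an estimated correlation), and Blvrb, a biliverdin reductase, rose 3.02-fold. Core macrophage genes had 16 of 27 higher and 6 lower (median 0.25, adjusted p = 0.00286, and adjusted p = 0.438 with an estimated correlation), with the complement gene C1qb up 3.50-fold to 752.7 ± 17.9 CPM and Cx3cr1 down. The osteoclast list had 6 of 11 higher and 3 lower (median 0.85, or 1.07 with genes of at most 3 counts at their bound, adjusted p = 0.0128, and adjusted p = 0.181 with an estimated correlation), including Dcstamp, a gene of cell fusion, up to 10.5 ± 1.25 from 0.583 ± 0.195 CPM. Of these 11 genes 4 are also in other lists. With total counts the medians of the lysosome, fatty acid oxidation, cholesterol efflux and core macrophage lists fell to 0.020, 0.030, 0.073 and 0.0076. Adjusted over the list alone, 42 oxidative phosphorylation genes were higher and 8 core macrophage genes lower, and the other counts of this paragraph were the same.

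Lists with no call as a whole in this comparison were S phase (6 of 49 higher, 9 lower, adjusted p = 0.457), mitosis (5 of 56 higher, 18 lower, adjusted p = 0.112, but 0.0248 without IL-4 replicate 3), glycolysis (7 of 26 and 13, adjusted p = 0.13), hypoxia (4 of 22 and 12, adjusted p = 0.115), cholesterol synthesis (10 of 24 and 5, adjusted p = 0.327) and the unfolded protein and amino acid response (17 of 38 and 17, adjusted p = 0.457). The last 2 had medians of 0.10 and 0.069, which turned to -0.14 and -0.17 with total counts, and means of -0.024 and -0.25. The mitochondrially encoded transcripts had 3 of 13 higher and 0 lower (adjusted p = 0.116, but 0.0276 without IL-4 replicate 1 and 0.0449 with no low-count filter). Their median of 0.19 turned to -0.059 with total counts. Examples are Pcna, the replication clamp, up 1.91-fold to 238.6 ± 4.80 CPM, Aldoc, a glycolytic aldolase, down 4.65-fold, Egln3, an oxygen-sensing hydroxylase, down 6.74-fold, and Phgdh, the first enzyme of serine synthesis, down 4.53-fold to 3.45 ± 0.776 CPM. All these counts were the same adjusted over the list alone, except 4 higher for mitosis.

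In all, 7229 of 14114 genes (51.22%) were called in this comparison at an adjusted p under 0.05 by edgeR's quasi-likelihood test, 3585 higher and 3644 lower, and 2192 of them changed at least 2-fold, 687 higher and 1505 lower. Scaling by total count shifted the median of all genes from about 0 to -0.246 on the log2 scale, and the split then became 1681 higher and 7222 lower, or 18.88% higher against 49.59%. On FPKM the share higher was 18.91% with a pseudocount of 1 and 18.85% with 0.1, so small changes in this comparison are relative to the TMM scaling. Reads of Chil3, Retnla, Rnase2a, Ccl8 and, in the later comparisons, Fpr3, Saa3, H2-M2 and the C-type lectin genes can be split with close relatives or left out, so their values are uncertain. The labels do not give the harvest time of the control cells, and of 33 lists tested 14 were called, 1 of them also with an estimated correlation.

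The main comparison asked what TMV-OEG8-Man, added after IL-4, changed in IL-4-treated macrophages. Inflammatory genes that were silent or nearly so after IL-4 rose to high levels. Nos2 rose to 269.7 ± 38.6 CPM (SD, n = 3) from 1 count in the IL-4 libraries together, a ratio of 28770 (95% counting interval 5164 to 1137000). Without IL-4 replicate 1, which held that count, it was at least 6469-fold higher, and without IL-4 replicate 2 or 3 the ratio was 19060 (3420 to 752700) or 19080 (3425 to 753700). Il1b rose 168.6-fold to 314.7 ± 23.6 CPM and Tnf 221.1-fold to 294.4 ± 35.2 CPM, and Il6 rose from 0 counts to 17.1 ± 1.25 CPM. Arg1, Chil3 and Retnla fell but stayed above control, Arg1 down 8.67-fold to 162.7 ± 17.3 CPM, Chil3 5.32-fold to 569.9 ± 23.1 CPM and Retnla 2.66-fold to 4531 ± 309 CPM. Mrc1, whose product binds mannose, fell 17.0-fold to 72.0 ± 4.39 CPM.

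Large rises were also those of Lcn2, which encodes an iron-siderophore-binding lipocalin, at 446.2 ± 18.2 CPM with a ratio of 47590 (8541 to 1880000) over 1 count, or at least 10520-fold without IL-4 replicate 3 and by a ratio of 31520 (5657 to 1245000) without IL-4 replicate 2, and of Calcr, the calcitonin receptor, Fpr3, a formyl peptide receptor family gene, and Mir155hg, the host transcript of a microRNA induced in inflammation. These last 3 had 0 counts after IL-4 and were at least 2887-fold, 2151-fold and 1458-fold higher, taking 3 counts over the group as the floor, or 1912-fold, 1424-fold and 965.3-fold without IL-4 replicate 2 and nearly the same without replicate 3. Acod1 rose 14190-fold to 2928 ± 136 CPM, Saa3, an acute-phase serum amyloid, 9367-fold to 17830 ± 905 CPM, and the chemokine gene Ccl5 9007-fold to 3884 ± 293 CPM. Large falls were those of Slco2b1, an organic anion transporter, from 82.9 ± 4.50 CPM to 0 counts, Abca9, a lipid transporter family gene, from 44.7 ± 0.534 CPM to 3 counts, and Bex1, by a ratio of 1137 (388.8 to 5516). Cd28, a T cell costimulatory receptor, fell from 56.4 ± 4.44 to 0.0806 ± 0.0628 CPM, Gprc5c, an orphan receptor, from 35.7 ± 1.57 CPM to 5 counts, all in TMV-OEG8-Man replicate 1, Scn3a from 29.5 ± 1.46 to 0.161 ± 0.136 CPM, the scavenger receptor gene Stab2 221.1-fold and the amino acid transporter gene Slc36a2 146.7-fold. Cd86 rose 10.4-fold to 44.9 ± 5.21 CPM and Il10 7.50-fold to 4.57 ± 1.13 CPM. Tgfb1 fell 1.80-fold to 208.7 ± 6.76 CPM and Il4ra 1.13-fold to 82.6 ± 5.13 CPM (adjusted p = 0.00136).

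All 37 measured type I interferon response genes rose, with a median of 4.63 (adjusted p = 7.59e-25, and 0.0475 with an estimated correlation). Ifit2 rose 898.3-fold to 1095 ± 140 CPM, and Ifi205, an interferon-induced gene with 1 count after IL-4, reached 14.5 ± 2.49 CPM. Of the 33 classical activation genes 30 rose, 2 fell and 1 was not called, with a median of 9.07, or 7.92 with genes of at most 3 counts at their bound (adjusted p = 6.77e-14, and 0.00484 with an estimated correlation). Lcn2, Nos2 and Acod1 led that list. Of 31 NF-kB targets and inflammatory cytokines 27 rose and 1 fell, with a median of 2.90 (adjusted p = 1.6e-10, and 0.0242 with an estimated correlation). Cxcl3 and Cxcl1, chemokines that attract neutrophils, rose 2335-fold and 517.0-fold to 306.5 ± 19.0 and 193.9 ± 8.29 CPM. MHC class I genes were higher in 17 of 19 cases and lower in 1, with a median of 2.22 (adjusted p = 1.14e-09, and 0.0242 with an estimated correlation), and Tap1, a peptide transporter, rose 14.8-fold to 370.6 ± 22.1 CPM. The Toll-like receptor and nucleic acid sensing list had 20 of 35 higher and 12 lower (median 0.48, adjusted p = 0.0262, and adjusted p = 0.422 with an estimated correlation), with Irf7, a transcription factor of the interferon response, up 127.1-fold to 1525 ± 105 CPM and Tlr2 up 13.6-fold to 423.5 ± 8.76 CPM. Of 11 MHC class II genes 4 rose and 6 fell, with a median of -0.31, a mean of 0.329 and no call as a list (adjusted p = 0.296). Among them Ciita, the master regulator of class II transcription, fell 2.47-fold. For these 6 lists the counts adjusted over the list alone were the same, except 7 lower for class II.

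The alternative activation list had 30 of 38 members lower, 5 higher and 3 not called, and its median member fell by 1.92 on the log2 scale (adjusted p = 2.47e-06, and 0.0174 with an estimated correlation). Clec10a, a galactose-binding lectin, fell 19.96-fold and Ptgs1, the constitutive cyclooxygenase, 18.1-fold to 10.3 ± 1.44 CPM, whereas Ccl22, a chemokine that attracts T cells, rose 71.6-fold to 30.2 ± 5.33 CPM. The profibrotic list had 26 of 36 members lower, 8 higher and 2 not called, and its median member fell by 0.94 on the log2 scale (adjusted p = 1.96e-05, and 0.0209 with an estimated correlation). Pdgfc, a growth factor for fibroblasts, fell 29.3-fold to 1.69 ± 0.521 CPM, and, named after their values were seen, Fn1 fell 9.64-fold to 467.2 ± 38.1 CPM and Timp2, an inhibitor of metalloproteinases, 7.62-fold to 163.8 ± 3.99 CPM. Tgfbi, a matrix protein induced by TGF-beta, rose 18.04-fold to 1242 ± 121 CPM. Stromal markers were low in the same libraries. The mean log2 CPM of 7 of them, Col1a1, Col1a2, Col3a1, Col5a1, Bgn, Tagln and Acta2, was 7.58 ± 0.106 in control, 5.54 ± 0.562 with IL-4 and 4.86 ± 0.387 with TMV-OEG8-Man (SD, n = 3). As a list of 19 genes the stromal markers had 4 higher, 10 lower and 5 not called, and were not called together (adjusted p = 0.164, but 0.0275 without IL-4 replicate 1). Kdr, the VEGF receptor, rose 8.33-fold, Dcn, the proteoglycan decorin, 4.44-fold, and Pecam1, an endothelial adhesion gene, fell 42.0-fold. Metalloproteinases and matrix-degrading enzymes had 9 of 23 higher and 13 lower, with a median of -0.26, a mean of 0.517 and no call as a list (adjusted p = 0.226). Mmp27 fell 21.4-fold and Mmp25, a membrane-anchored protease, rose from 0 counts to 2.97 ± 0.116 CPM. Among 24 mannose-binding and C-type lectin receptors 16 fell and 8 rose, with a median of -0.93 (adjusted p = 0.0971, and 0.0422 with no low-count filter). Clec4e rose 4931-fold to 4623 ± 139 CPM, Marco, a scavenger receptor for bacteria, from 0 counts to 5.67 ± 0.520 CPM, and Ly75, an endocytic receptor, 42.0-fold. Adjusted over the list alone these counts were the same.

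**Figure D2:**
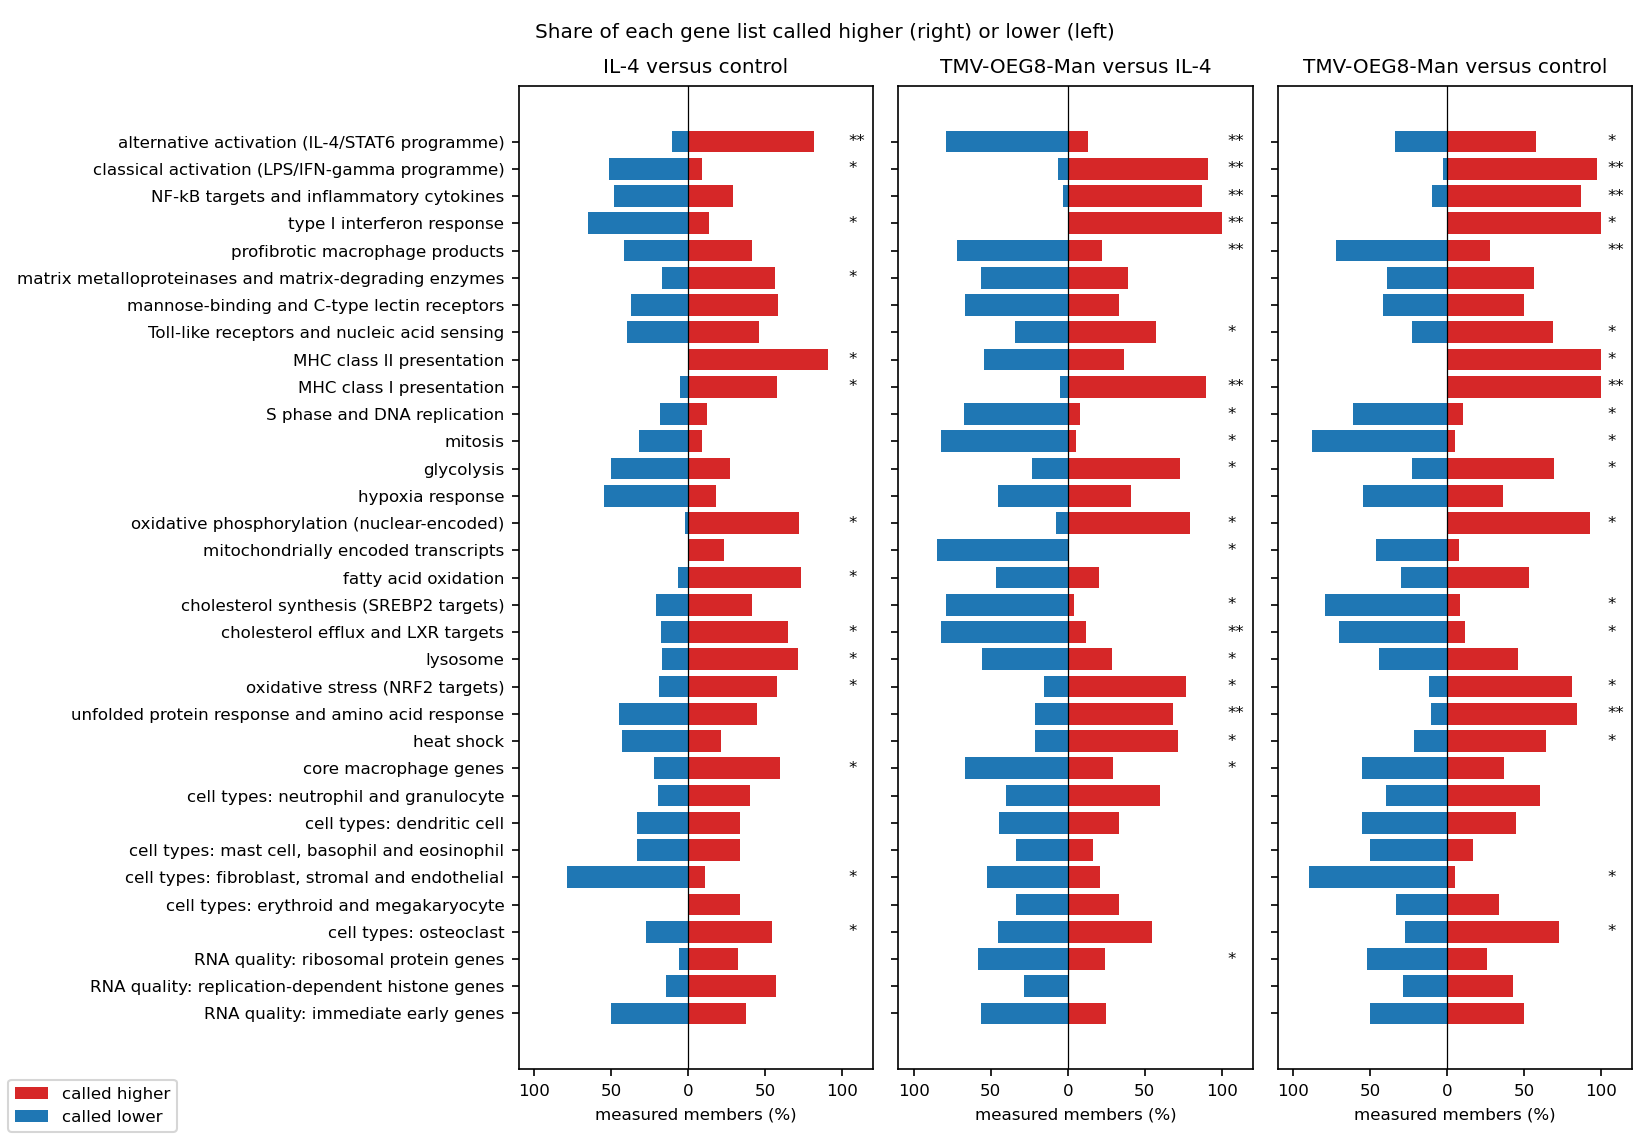
Percent of the measured members of each list called higher (red, right) or lower (blue, left) in the 3 comparisons, with 1 star for a camera adjusted p under 0.05 and 2 where it also held with an estimated correlation. All 37 interferon genes were higher with TMV-OEG8-Man than with IL-4, and 26 of 36 profibrotic genes lower.

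Cell cycle genes fell. Of 56 mitosis genes 46 fell and 3 rose, and the median member fell by 1.51 on the log2 scale (adjusted p = 2.7e-07, and adjusted p = 0.373 with an estimated correlation). Cenpa, the centromeric histone, fell 24.7-fold to 1.73 ± 0.614 CPM, and Kif11, a spindle motor, 22.7-fold. Of 49 S phase genes 33 fell and 4 rose, the median member falling by 0.48 (adjusted p = 0.00204, and adjusted p = 0.39 with an estimated correlation), with Rrm2, a subunit of ribonucleotide reductase, down 7.35-fold. Both lists had the same counts adjusted over the list alone.

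Sterol genes fell as well. Of 24 cholesterol synthesis genes 19 fell and 1 rose, and the median member fell by 0.90 on the log2 scale (adjusted p = 3.03e-06, and adjusted p = 0.31 with an estimated correlation). Dhcr7, the last enzyme of one branch of the pathway, fell 3.20-fold to 20.5 ± 1.68 CPM and Hmgcs1, the synthase of HMG-CoA, 3.04-fold. Of 17 cholesterol efflux and LXR targets 14 fell and 2 rose, the median member falling by 1.40 (adjusted p = 1.82e-05, and 0.0219 with an estimated correlation), including Arl4c, a small GTPase, down 9.08-fold, and Mylip, a ligase that degrades the LDL receptor, down 5.00-fold. The lysosome list had 29 of 52 lower and 15 higher (median -0.29, adjusted p = 0.0162, and adjusted p = 0.673 with an estimated correlation), where Atp6v0d2 fell 5.88-fold and Acp5 rose a further 7.37-fold to 1138 ± 36.9 CPM. Core macrophage genes had 18 of 27 lower and 8 higher (median -0.94, adjusted p = 0.00129, and adjusted p = 0.39 with an estimated correlation). Ccr2, the receptor that recruits monocytes, fell 71.0-fold to 0.272 ± 0.0796 CPM. Adjusted over the list alone these counts were the same.

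Of 38 unfolded protein and amino acid response genes 26 rose and 8 fell, with a median of 0.66 (adjusted p = 9.14e-05, and 0.0407 with an estimated correlation). Phgdh rose 82.7-fold to 286.2 ± 11.7 CPM and Mthfd2, a mitochondrial folate enzyme, 25.2-fold to 222.0 ± 3.92 CPM. NRF2 targets had 20 of 26 higher and 4 lower (median 0.72, adjusted p = 3.68e-05, and adjusted p = 0.31 with an estimated correlation), with Slc7a11, the cystine transporter, up 17.2-fold to 553.8 ± 17.4 CPM. Glycolysis had 19 of 26 higher and 6 lower (median 0.58, adjusted p = 0.000402, and adjusted p = 0.31 with an estimated correlation), with Pfkfb3, an activator of phosphofructokinase, up 6.46-fold to 385.0 ± 27.0 CPM. Nuclear-encoded oxidative phosphorylation had 42 of 53 higher and 4 lower (median 0.36, adjusted p = 2.47e-06, and adjusted p = 0.39 with an estimated correlation), while the mitochondrially encoded transcripts had 11 of 13 lower and 0 higher (median -0.62, adjusted p = 0.00545, and adjusted p = 0.422 with an estimated correlation). Cycs, cytochrome c, rose 3.81-fold, and ND1, a subunit of complex I, fell 1.77-fold to 1241 ± 74.6 CPM. Fatty acid oxidation genes had 6 of 30 higher and 14 lower (median -0.21, adjusted p = 0.0802, and 0.0484 with no low-count filter), but Acsl1, which activates long-chain fatty acids, rose 99.7-fold to 4150 ± 241 CPM. The hypoxia list had 9 of 22 higher and 10 lower, with a median of -0.30, a mean of 0.327 and no call (adjusted p = 0.642). Ndrg1 in it fell 19.6-fold. Adjusted over the list alone, 43 oxidative phosphorylation genes were higher and 11 hypoxia genes lower, and the other counts were the same.

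In total 9771 of 14114 genes (69.23%) were called, 5039 higher and 4732 lower, and 3739 changed at least 2-fold, 1646 higher and 2093 lower. Scaling by total count shifted the median of all genes to -0.110 on the log2 scale and turned the direction of no called list, but the split became 4159 higher and 5587 lower, or 42.67% higher against 51.57%. The share was 45.82% with upper-quartile scaling, 49.49% with RLE size factors, 49.23% with DESeq2, 44.02% on log2(FPKM + 1) and 43.37% on log2(FPKM + 0.1), so which direction held more calls depended on the scaling. Of 33 lists 20 were called, 8 of them also with an estimated correlation. By the labels these cells had 24 h more of treatment and a change of medium, neither the harvest of the IL-4 cells relative to it nor whether IL-4 was kept is given, and no group with unmodified virus, endotoxin or fresh medium alone after IL-4 was analysed here, so the changes belong to the treatment as a whole.

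The comparison of the TMV-OEG8-Man group with control asked how far these cells lay from resting macrophages. Their libraries held transcripts of both activation programmes, and bulk RNA does not tell whether the same cells made both. Arg1 at 162.7 ± 17.3 CPM was still 381.7-fold above control (SD, n = 3), Chil3 1266-fold and Retnla 2608-fold. Nos2 stood at 269.7 ± 38.6 CPM and Il12a, a subunit of interleukin-12, at 97.8 ± 7.69 CPM, both with 0 counts in control. Mrc1 was 2.07-fold lower than in control and Tgfb1 1.215-fold lower.

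Il1b was 16.8-fold and Tnf 24.6-fold above control, Il10 48.3-fold, or by a ratio of 127.3 (43.3 to 619.4) without control replicate 1, Cd86 2.02-fold, and Il6 by a ratio of 723.0 (247.0 to 3509) over 3 counts. Calcr and Fpr3 were at least 3427-fold and 2554-fold higher, or 2260-fold and 1684-fold without control replicate 1 and nearly the same without replicate 2. Cxcl3 stood at 306.5 ± 19.0 against 0.0321 ± 0.0374 CPM in control, and Lcn2 at 446.2 ± 18.2 against 0.0544 ± 0.0484 CPM. H2-M2, a nonclassical class I gene, was 8669-fold higher at 958.4 ± 23.2 CPM, and Cfb, complement factor B, 7425-fold at 7680 ± 377 CPM. Slco2b1 and Gpr34, a lysophospholipid receptor, had 0 counts, against 23.3 ± 1.44 and 21.8 ± 1.44 CPM in control. Cx3cr1 fell 2399-fold to 0.0605 ± 0.0301 CPM and Cd28 from 140.6 ± 5.45 to 0.0806 ± 0.0628 CPM. Abca9 and Bex1, with 3 counts each, came from 20.5 ± 1.47 and 18.4 ± 1.62 CPM in control, Lrrc14b went from 36.5 ± 2.23 to 0.0708 ± 0.0632 CPM and Pcp4l1 from 21.6 ± 1.59 to 0.0807 ± 0.0630 CPM. Il4ra was 1.23-fold lower (adjusted p = 2.36e-06).

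All 37 interferon genes were higher than in control, with a median of 3.78 (adjusted p = 2.75e-23, and adjusted p = 0.0624 with an estimated correlation), as were 32 of 33 classical activation genes with 1 lower (median 7.42, adjusted p = 7.79e-15, and 0.00401 with an estimated correlation) and 27 of 31 NF-kB targets with 3 lower (median 2.46, adjusted p = 4.36e-10, and 0.0367 with an estimated correlation). All 19 MHC class I genes rose (median 2.44, adjusted p = 1.47e-12, and 0.0241 with an estimated correlation), and all 11 MHC class II genes (median 3.19, adjusted p = 2.99e-08, and adjusted p = 0.104 with an estimated correlation), with H2-DMb1, a chain of the peptide-exchange factor, up 24.0-fold. The alternative activation list had 22 of 38 higher and 13 lower (median 1.78, adjusted p = 0.0261, and adjusted p = 0.104 with an estimated correlation). The unfolded protein and amino acid response had 32 of 38 higher and 4 lower (median 0.83, adjusted p = 1.15e-08, and 0.0241 with an estimated correlation). Adjusted over the list alone these counts were the same.

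Profibrotic genes were lower than in control in 26 of 36 cases and higher in 10, and the median member fell by 1.23 on the log2 scale (adjusted p = 0.000774, and 0.0367 with an estimated correlation). The 10 include Arg1 and Ccl24, up 381.7-fold and 191.2-fold, and Ccl22 at 30.2 ± 5.33 CPM, up 637.1-fold over 6 control counts. Those 6 counts were all in control replicate 3. The ratio was 420.2 without control replicate 1 and 423.3 without control replicate 2, and only bounded, at 861.6 or more, without control replicate 3. Stromal, fibroblast and endothelial markers were lower in 17 of 19 cases and higher in 1 (median -2.14, adjusted p = 3.49e-05, and adjusted p = 0.292 with an estimated correlation), among them Acta2, smooth muscle actin, down 14.6-fold to 20.2 ± 4.14 CPM, and Cxcl12, a stromal chemokine, 12.5-fold. Mitosis genes were lower in 49 of 56 cases and higher in 3 (median -1.96, adjusted p = 6.56e-09, and adjusted p = 0.27 with an estimated correlation), including the kinesins Kif4 and Kif2c, 36.9-fold and 34.4-fold. S phase genes were lower in 30 of 49 cases and higher in 5 (adjusted p = 0.00154, and adjusted p = 0.351 with an estimated correlation). Cholesterol synthesis had 19 of 24 lower and 2 higher (adjusted p = 2.3e-05, and adjusted p = 0.27 with an estimated correlation), and cholesterol efflux and LXR targets 12 of 17 lower and 2 higher (adjusted p = 0.00151, and adjusted p = 0.0555 with an estimated correlation), with Scd1, a fatty acid desaturase, down 8.55-fold. The 6 lists had the same counts adjusted over the list alone, except 3 higher for cholesterol synthesis.

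Also higher than in control were oxidative phosphorylation, with 49 of 53 up and 0 down (adjusted p = 2.5e-11, and adjusted p = 0.244 with an estimated correlation), NRF2 targets, 21 of 26 and 3 (adjusted p = 2.6e-07, and adjusted p = 0.204 with an estimated correlation), glycolysis, 18 of 26 and 6 (adjusted p = 0.00301, and adjusted p = 0.323 with an estimated correlation), Toll-like receptors and nucleic acid sensing, 24 of 35 and 8 (adjusted p = 0.00466, and adjusted p = 0.34 with an estimated correlation), and the osteoclast list, 8 of 11 and 3 (adjusted p = 0.0418, and adjusted p = 0.227 with an estimated correlation). Hk3, a hexokinase of myeloid cells, rose 5.22-fold to 846.0 ± 45.3 CPM. Lists without a call were lysosome (24 of 52 higher, 23 lower, adjusted p = 0.771), fatty acid oxidation (16 of 30 and 9, adjusted p = 0.491), metalloproteinases (13 of 23 and 9, adjusted p = 0.413), C-type lectins (12 of 24 and 10, adjusted p = 0.611) and hypoxia (8 of 22 and 12, adjusted p = 0.259). The lectin median was -0.043, or 0.27 with genes of at most 3 counts at their bound, against a mean of 0.61, and the hypoxia median was -0.16 against a mean of 0.052. Mitochondrially encoded transcripts had 1 of 13 higher and 6 lower (adjusted p = 0.0556), a list that was called without control replicate 2 (0.0439), IL-4 replicate 1 (0.0488) or 2 (0.036), TMV-OEG8-Man replicate 3 (0.0369), or the low-count filter (0.0381). Core macrophage genes had 10 of 27 higher and 15 lower (adjusted p = 0.0505). That list was called without control replicate 1 (0.0474), 2 (0.0413) or 3 (0.0443), IL-4 replicate 1 (0.0402) or 2 (0.0445), TMV-OEG8-Man replicate 2 (0.0445), or the low-count filter (0.045). When adjusted over the list alone, 19 glycolysis genes were higher and 13 hypoxia genes lower, and the other counts were the same.

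Of 14114 genes, 10069 (71.34%) were called between TMV-OEG8-Man and control, 5157 higher and 4912 lower, and 4010 at least 2-fold. Scaling by total count shifted the median of all genes to -0.346 on the log2 scale and the split to 2770 higher and 7817 lower, or 26.16% higher against 51.22%. The share was 40.99% with upper-quartile scaling, 26.56% on log2(FPKM + 1) and 26.33% on log2(FPKM + 0.1). Of 33 lists 19 were called, 5 of them also with an estimated correlation.

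The last question was how many of the genes changed by IL-4 moved back with TMV-OEG8-Man. Among the 3585 genes raised by IL-4, 2038 fell with TMV-OEG8-Man and 941 rose further, and among the 3644 lowered by IL-4, 1736 rose and 965 fell further. Arg1, Chil3, Retnla, Mrc1, Fn1 and Tgfb1 were raised and then fell, and Il1b, Tnf, Cd86, Clec4e and Acod1 were lowered and then rose. Cx3cr1, lowered 50.6-fold by IL-4, fell a further 47.4-fold, and Acp5, raised 10.7-fold, rose further. In all 3774 genes, 52.2% of those changed by IL-4, moved back and 1906 moved further in the same direction, while 4091 genes that IL-4 did not change by this test were called with TMV-OEG8-Man.

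**Figure D3:**
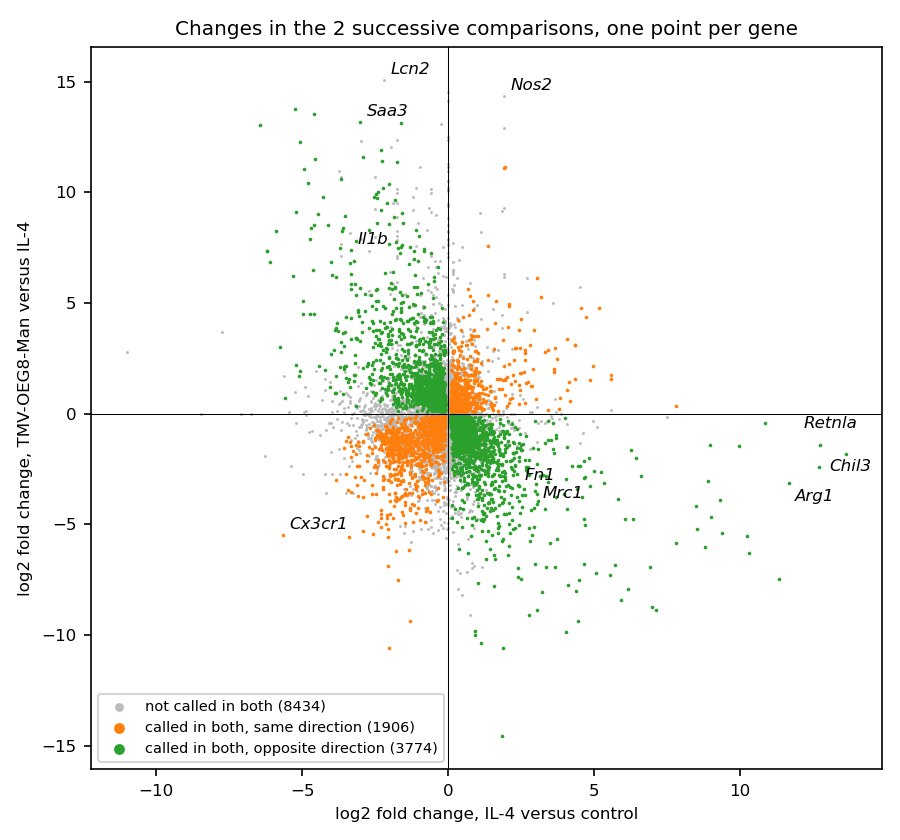
Log2 fold change of each of 14114 genes from control to IL-4 (horizontal) and from IL-4 to TMV-OEG8-Man (vertical), one point per gene, colored by whether both comparisons called it in opposite directions (green), in the same direction (orange) or not both (grey). The green points number 3774 and the orange 1906; fitted values of genes with 3 or fewer counts in a group, such as Nos2 and Lcn2, depend on the prior count.

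Moving back did not always end at the control level. Of the 2038 genes that rose and fell, 1122 (55.05%) were called below control, 592 (29.05%) were not told from control and 324 (15.9%) were still called above it. Mrc1 is among the first and Arg1 among the last. Of the 1736 that fell and rose, 1042 (60.02%) were called above control, among them Il1b, Tnf and Clec4e. Among genes changed at least 2-fold by IL-4 the shares past control were lower, with 212 of 479 (44.26%) called below it and 230 of 467 (49.25%) above it, and those short of it higher, with 137 (28.6%) still above and 126 (26.98%) still below, against 15.9% and 12.1% of all. These differences were not tested.

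Both comparisons hold the IL-4 libraries with opposite signs, which by itself sets their fold changes against each other. In 20 simulations without any effect a mean of 0.3 genes moved back. These called a mean of only 0.55 genes raised and 0.75 lowered by IL-4, so almost none could move back. That count is thus no measure of what the shared libraries add to the observed number. Lists drawn independently with the observed numbers of calls would share 1201.9 genes raised then lowered and 1301 lowered then raised, against 2038 and 1736. For movement further in the same direction such lists would share 1279.9 and 1221.7 genes, against 941 and 965. The covariance of the fold changes across genes, which are not independent replicates, was -0.455 against -0.031 in the simulations, and Pearson's r was -0.249 against -0.501. The simulated r comes from the shared libraries alone and was stronger than the observed one, so the observed r is not a sign of moving back. With 3 IL-4 libraries no split leaves 2 in each part, so part of the excess may come from the shared libraries. Of the genes that moved back, 46% had been lowered by IL-4 with TMM and 69.97% with total counts, where the numbers were 1203 raised then lowered and 2803 lowered then raised, and the share was 68.72% and 69.95% on FPKM with pseudocounts of 1 and 0.1.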

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

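Scaling by total count was chosen after the data were seen; the other alternatives were planned. Over RLE and upper-quartile factors, the filters, DESeq2, limma-voom, 2-group fits, the replicate block, FPKM and total counts, calls numbered 6810 to 8903 for IL-4 versus control, 9192 to 10106 for TMV-OEG8-Man versus IL-4, 9283 to 10597 for TMV-OEG8-Man versus control and 3612 to 4006 moved back. The genes called were less alike than these totals. Of the 7229 for IL-4 versus control, 6584 were also called with upper-quartile scaling, 5564 with total counts and 5430 on log2(FPKM + 1). With total counts 8891 of 9771 and 8347 of 10069 were also called in the other 2 comparisons. Leaving out 1 library in turn gave 6474 to 7369, 9367 to 9804, 9602 to 10276 and 3439 to 3737, and 14 to 15, 19 to 20 and 19 to 21 called lists. Asking also for at least 2-fold left 2192, 3739, 4010 and 797 by construction. With an estimated correlation 1, 8 and 5 lists were called. With fry 26, 30 and 33 were called, and fry tests another question than camera. Its direction for the mast cell, basophil and eosinophil list was opposite, with an adjusted p of 0.000945 (TMV-OEG8-Man versus IL-4) and 0.00366 (TMV-OEG8-Man versus control); the cause was not tested. Among the named genes reported for IL-4 versus control 2 small rises became negative on log2(FPKM + 1), log2(FPKM + 0.1) and total counts, namely ND4 (-0.05162, -0.05167 and -0.04865) and Rplp2 (-0.06056, -0.06068 and -0.05961), since these scalings leave out the composition factor of TMM. Of the named genes of that comparison 102 of 112 kept direction and call under every alternative that gave them a value (the 2-fold condition was not run on them, and 2, 1 and 1 genes lacked a value under some setting), against 115 of 118 in TMV-OEG8-Man versus IL-4 and 111 of 114 in TMV-OEG8-Man versus control. For lists and the alternatives run on them it was 5, 11 and 5 of 33. Genes at 0 to 3 counts limit folds to bounds.

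The labels number the replicates alike in each group, but the deviations of same-numbered libraries were paired only weakly, with correlations of -0.0442 to 0.129, and 3 of 9 libraries correlated best with their own number. With the replicate block the counts were 7175, 9730, 10030 and 3739, and 14, 20 and 19 lists, and it changed no call of a list or named gene.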

Other observations

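Tests of a loss of the IL-4 effect, of longer treatment, of neutrophils and of a few genes taking most of the counts were chosen only after the results were seen; that of stromal cells was written before. Heat shock genes were higher with TMV-OEG8-Man than with IL-4, with 10 of 14 members higher and 3 lower and a median of 0.70 (camera adjusted p = 0.0116, and adjusted p = 0.31 with an estimated correlation). The chaperonin genes Hspe1 and Hspd1 rose 2.97-fold and 2.44-fold, to 83.9 ± 6.39 and 243.8 ± 12.4 CPM (SD, n = 3). Against control 9 rose and 3 fell (adjusted p = 0.0261, and adjusted p = 0.292 with an estimated correlation), while IL-4 alone gave 3 and 6 (adjusted p = 0.443), with a median of 0.032 that turned to -0.21 with total counts and -0.026 with upper-quartile scaling and a mean of -0.43. Of 50 ribosomal protein genes 29 fell and 12 rose with TMV-OEG8-Man against IL-4 (median -0.15, adjusted p = 0.0262, and adjusted p = 0.673 with an estimated correlation), a call lost without IL-4 replicate 1 (0.0665) or TMV-OEG8-Man replicate 1 (0.0671). Against control 13 rose and 26 fell (adjusted p = 0.123), and IL-4 against control gave 16 and 3 (adjusted p = 0.177, but 0.025 without IL-4 replicate 2). Histone genes (7 measured) had 4 higher and 1 lower with IL-4 against control (adjusted p = 0.115), 0 and 2 with TMV-OEG8-Man against IL-4 (0.352) and 3 and 2 against control (0.542). Immediate early genes (16 measured, of which Atf3 is in another list) had 6 and 8, 4 and 9, and 8 and 8 (adjusted p = 0.67, 0.199 and 0.984), and in the first and last of these the test pointed up while median and mean were negative. The phosphatase gene Dusp1 rose 6.48-fold to 173.4 ± 9.90 CPM with TMV-OEG8-Man, and Zfp36, which destabilises cytokine transcripts, fell from 186.3 ± 6.02 to 61.5 ± 7.31 CPM. Chosen after its values were seen, the proliferation marker Mki67 rose 4.36-fold to 213.5 ± 2.599 CPM with TMV-OEG8-Man (edgeR adjusted p = 5.41e-06), while 46 of the 56 mitosis genes it is listed with fell. Adjusted over the list alone, ribosomal protein genes had 12 higher with IL-4, and the other counts of this paragraph were the same.

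Markers of other cell types moved in both directions. The counts that follow are higher and lower in IL-4 versus control, TMV-OEG8-Man versus IL-4 and TMV-OEG8-Man versus control, with camera adjusted p. Neutrophil markers (5 measured, 2 of them, Lcn2 and Mmp8, in other lists) had 2 and 1, 3 and 2, and 3 and 2 (0.615, 0.727 and 0.491), and the median with IL-4 was 0.18, or -0.76 with genes of at most 3 counts at their bound, against a mean of -0.42. Dendritic cell markers (9, of which Batf3, Cd209a and Kit are in other lists) had 3 and 3, 3 and 4, and 4 and 5 (0.763, 0.642 and 0.542), and Cd24a in it returned from 2.43 ± 0.352 to 55.7 ± 2.55 CPM with TMV-OEG8-Man. With IL-4 that list's median of 0.073 turned to -0.17 with total counts, and its test pointed down. Mast cell, basophil and eosinophil markers (6) had 2 and 2, 1 and 2, and 1 and 3 (0.763, 0.642 and 0.44), with a median of -0.39 and a mean of 0.38 in the middle comparison. Siglecf, an eosinophil and macrophage lectin, fell 33.5-fold to 0.303 ± 0.152 CPM there, and Hdc, histidine decarboxylase, rose from 0 counts to 3.99 ± 0.915 CPM. Erythroid and megakaryocyte markers (6) had 2 and 0, 2 and 2, and 2 and 2 (0.45, 0.633 and 0.564), the last with a median of -0.34 and a mean of 0.37, and the platelet chemokine gene Pf4 rose 2.39-fold to 209.4 ± 9.90 CPM with TMV-OEG8-Man against IL-4. Osteoclast genes against IL-4 had 6 higher and 5 lower (0.642), with the protease gene Mmp9 up 15.6-fold to 53.3 ± 2.84 CPM. B cell (3 measured) and T and NK cell (2) lists were too small to test, with 2 and 1, 0 and 3, and 0 and 2 for the first and 0 and 1, 1 and 1, and 1 and 1 for the second. Cd22, a B cell lectin, fell 4.36-fold with TMV-OEG8-Man against IL-4 and Cd4 6.41-fold. The mast list had 3 lower in the first comparison and the erythroid list 1 lower in the middle one when adjusted over the list alone, and the other counts were the same.

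The 26 profibrotic genes lower with TMV-OEG8-Man than with IL-4 could reflect fewer stromal cells in the culture. The mean of 7 stromal markers went from 5.54 ± 0.562 to 4.86 ± 0.387 (SD, n = 3), though the stromal list was not called in this comparison. With the score of these 7 markers as a covariate, 25 of the 26 stayed called lower, the median of the 26 going from -1.44 to -1.51. The list kept a camera adjusted p of 8.46e-06. For these 25 this argues against fewer stromal cells as the whole cause, as far as the score tracks such cells. The slope on the score rests only on the scatter within groups of 3 libraries, so the correction is uncertain. The call of Tgfb3 ended, from -1.28 ± 0.34 to -0.44 ± 0.259 (SE), because its fold shrank, and Sparc, Thbs1 and Spp1 shrank from -0.65, -0.81 and -1.21 to -0.20, -0.50 and -0.98, so a stromal part stays open for these 4. Of the 12 among them that IL-4 had raised, 9 were called below control, though Ctsb and Cd63 only by log2 fold changes of -0.11 and -0.1875. A loss of the IL-4 effect that only returned genes to the level of these controls would not give this. Whether such a loss stops at that level was not tested. The stromal score was also higher in control, at 7.58 ± 0.106 (SD, n = 3), and the covariate was not used in the comparison with control. A stromal part in the control level of these 9 genes thus stays open. For the other 3, Arg1, Ccl24 and Igf1, a loss of the IL-4 effect cannot be told apart from an effect of TMV-OEG8-Man. The 9 include Apoc1, not called as raised with DESeq2, upper-quartile scaling, FPKM or total counts or without control replicate 1 (adjusted p = 0.182) or 3 (0.0575) or IL-4 replicate 1 (0.0825) or 3 (0.149), and not called below control with only the 2 groups compared, and Trem2, not called as raised with FPKM or total counts. Over all settings but the 2-fold condition 7 to 10 were below control, and without TMV-OEG8-Man replicate 1 it was 8, with Ctsb lost. Longer treatment, the change of medium and a response to the particle were not separated by the design, were not tested and stay open.

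Among 2038 genes raised by IL-4 and lower with TMV-OEG8-Man, 55.05% were called below control. A loss of the IL-4 effect that only returned genes to the level of these control libraries would not give this. Whether such a loss stops at that level was not tested. Whether the higher stromal score in control adds to these falls was not tested either. A few genes taking most of the counts may push others down. The 100 genes of most counts in the TMV-OEG8-Man libraries hold 31.57% of the counts there and 23.7% of control. Picking them by those libraries itself favours a larger share there. In counts scaled by total this lowers all others by at most 0.157 on the log2 scale. Of 1115 genes called below control, these 100 aside, 895 lay lower than that by over 2 SE and 220 did not, with a median of -0.59 over the 1115. These falls are TMM-scaled, which already takes up part of such a push, so the 2 are not on the same scale. The shift of all genes between TMM and total counts was also larger than 0.157, so the comparison does not decide what scaling adds to the falls. For the 916 genes not called below control a loss of the IL-4 effect cannot be told apart from an effect of TMV-OEG8-Man. No group had IL-4 withdrawn without TMV-OEG8-Man, and whether IL-4 was kept with TMV-OEG8-Man is not given. The 24 more hours of treatment in the labels cannot be told apart from TMV-OEG8-Man for any of these genes, and the labels do not give the age of the cells at harvest.

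Lcn2, S100a8 and Camp, genes of neutrophil granules or cytoplasm, were higher with TMV-OEG8-Man, with 44210, 3063 and 107 counts over 3 libraries against 1, 145 and 1 with IL-4. Neutrophils in the cultures could bring such transcripts. Of the 11 other matched members of the neutrophil list, Mmp8 and Csf3r were already expressed in control and IL-4 libraries, where a small share of neutrophils would not show. The 9 under 1 CPM in both groups (S100a9, Ly6g, Ngp, Ltf, Elane, Prtn3, Ctsg, Cxcr2 and Chil1) were picked without use of the TMV-OEG8-Man libraries. They had 11 counts together in those, 0.0232% of the 3 genes, against 52 with IL-4 and 27 in control. Since Lcn2 holds 44210 of the 47380 counts of the 3 genes, this argues against neutrophils as the source of Lcn2. S100a8 rose from 145 counts with IL-4 to 3063, while those 9 genes fell together from 52 to 11, with 0 for S100a9. This argues against neutrophils as the source of most S100a8 counts too, as far as neutrophils carry those 9. For Camp, with only 107 counts, the share does not decide. Expression by the macrophages themselves was not tested.

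The 10 splits of 6 libraries into 3 and 3 are too few for a share under 0.05. In each comparison 1 of the 10, the real one, gave as many genes, with 7229, 9771 and 10069 against a highest other of 0, and as many lists, with 14, 20 and 19 against 13, 16 and 17. All other splits mix the 2 groups, which widens the spread within each part, so few gene calls could come from them. Lists were nevertheless called in splits where no gene was, so the number of called lists hardly sets the real split apart. For the moved-back genes 1 of 100 draws of the 9 libraries into 3 groups, the real one, gave as many, with 3774 against a highest other of 948. No draw called as many genes in both comparisons as the real groups, since draws mix the treatments, so this does not show that more genes moved back than the numbers of calls would give.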
